A study of Glycine max with 2 samples.

How the data were processed

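Small RNA was sequenced from the shoot tips of soybean (Glycine max) plants of 2 isolines in the Clark background: the standard line, whose leaves have the usual leaflet number (trifoliate), and a five-foliate mutant line. Per the labels' protocols, young shoot tips were taken from several greenhouse plants aged 4 weeks, total RNA was extracted with phenol and chloroform without lithium chloride precipitation, and libraries were sequenced on an Illumina HiSeq instrument. The labels give 1 library per isoline, so there is no replicate error for any difference between the isolines.

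The deposited table, per its file header, holds total small RNA counts: the authors' number of reads for each distinct sequence in each library, as whole numbers with no normalization. Bowtie is named in the submitters' processing notes without a version or a role. The adapter trimming, any length limits and filters, and a genome build are not given in the sources used here. The sequences in the table run from 16 to 25 nt, and 2863 of the 308702 distinct sequences hold an uncalled base (N). A distinct sequence with its counts is called a tag below. The counts sum to 9995215 reads in the trifoliate library and 9797273 in the five-foliate library. With 3 reads taken as the limit that a count of 0 allows, the floors were 0.300 and 0.306 reads per 1000000 (RPM). PCR reads without molecular identifiers are not independent molecules, so all intervals and floors cover counting error only.

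Counts were scaled to reads per 1000000 of all reads in the table. Ratios are five-foliate over trifoliate, with an exact 95% interval for the ratio of 2 Poisson counts (Clopper-Pearson on the share of the counts from each library). Shares carry Wilson 95% intervals. No p-value was computed for the isolines, because a test on the reads of 2 libraries compares those libraries and not the genotypes. In place of a test, a family or tag was set apart by size when it had 100 or more reads over both libraries and its whole interval lay beyond 2-fold.

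The reads of a microRNA family were summed over tags of 19 to 24 nt that equal a listed mature sequence or differ from it by up to 2 bases added or removed at each end, with no internal mismatch. A tag that fitted more than 1 family went to none. The list of 50 families (the TAS3 trans-acting siRNA and 6 star strands, the partner strands of the microRNA duplex, included) and its division into 6 lists were fixed from general knowledge: leaf development, nutrient and stress, triggers of NB-LRR gene silencing, silencing feedback, other microRNAs and star strands. A family with 10 or more reads counted as measured. The median log2 ratio of a list, on counts with 0.5 added, was placed among the medians of 10000 random lists of as many tags, each within a factor of 1.5 of its member's reads. Where too few tags lay in that range, the nearest in reads were used instead. The random tags were single tags outside the listed families, without N but with near-copies kept, while a family's reads are a sum over its tags. The percentile describes these 2 libraries and is not a test of the isolines. Breakdown fragments were tags that are exact parts of 4 transfer RNAs or of 5.8S ribosomal RNA. A near-copy is a tag that differs by 1 base from a tag with at least 20 times its reads, and 51575 tags were near-copies.

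No genome was used here, so tags were not placed on chromosomes and the planned count of reads by genomic origin was not run. A RefSeq gene table (Glycine_max_v4.0) was used only to count the annotated microRNA genes of a family. Reads of identical mature sequences cannot be divided between those genes.

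The text names microRNA families and tags by a rule. Families with 1000 or more reads may be given with levels. Ratios are given for the 8 most abundant families, for up to 8 families set apart in each direction with the largest ratios, and for all members of the leaf development list; the levels behind a ratio stand beside it in places, also for families with fewer reads. Of single tags, the 5 with the largest ratio in each direction among those set apart were taken. The sequences of the tags lower in the five-foliate library are not printed, because their organism of origin was not checked. These rules, the lists, the main scale and most alternatives were fixed before the data were examined. The alternatives fixed then were edgeR's TMM scaling, DESeq2's median of ratios, scaling to reads of 20 to 24 nt, to reads of listed families or to reads without the 10 most abundant tags of each library, other family definitions, other read minimums and other fold limits. Chosen after seeing the data were a scaling of each read length by its own median ratio, random lists matched on length, and the removal of N tags and near-copies.

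The size rule was tested on simulated Poisson counts for 305839 tags with the real totals. It recovered 100 of 100 tags changed 4-fold and 89 of 100 changed 3-fold. The changed tags were drawn from tags with more reads than the rule's minimum of 100, so recovery near that minimum was not measured. It set apart 0 of 13701 unchanged tags, which counting error alone makes nearly certain at these read numbers. Biological variation was not simulated. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.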

Results

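Small RNA reads from shoot tips of 4-week-old trifoliate and five-foliate soybean isolines were compared, with 1 library per isoline. The question, from the series' title, was how small RNAs vary between shoot tips that form leaves with the standard and with the mutant leaflet number. The trifoliate library held 9995215 reads in 200446 distinct tags, and the five-foliate library 9797273 reads in 268506 distinct tags. There were no replicates, so every difference below is a difference between 2 libraries with no replicate check.

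The first comparison asked whether the size classes of small RNA differed. In plants, microRNAs and trans-acting siRNAs are mostly 21 or 22 nt long, and 24-nt siRNAs direct DNA methylation. The 24-nt reads made up 2.74% of the trifoliate library (Wilson 95% interval 2.73 to 2.75) and 10.2% of the five-foliate library (10.1 to 10.2), a ratio of 3.71. The 21-nt reads differed little, at 11.9% and 12.3%, while 22-nt reads were at 7.26% and 10.95%. By reads, the ratio was not special to the 24-nt class: it was 2.12 for 23-nt reads and 4.30 for 25-nt reads. Reads of 16 nt fell from 14.0% to 8.28%, and reads of 20 nt from 21.5% to 16.3%. Among distinct tags, 24-nt sequences were 18.2% in the trifoliate and 34.6% in the five-foliate library. The neighbouring lengths differed less by this measure, at 7.68% and 7.71% for 23 nt and 4.64% and 5.72% for 25 nt. Shares of distinct tags also depend on how many reads each class has. Of all distinct 24-nt tags, 44.3% began with A, the 5′ base favoured by the Argonaute proteins that bind 24-nt siRNAs. By reads, A began 31.0% of trifoliate and 33.9% of five-foliate 24-nt reads, below its 40.8% and 38.7% of 21-nt reads. Of distinct 22-nt tags, 39.7% began with T. The mean read length was 19.4 nt in the trifoliate and 20.5 nt in the five-foliate library.

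**Figure D1:**
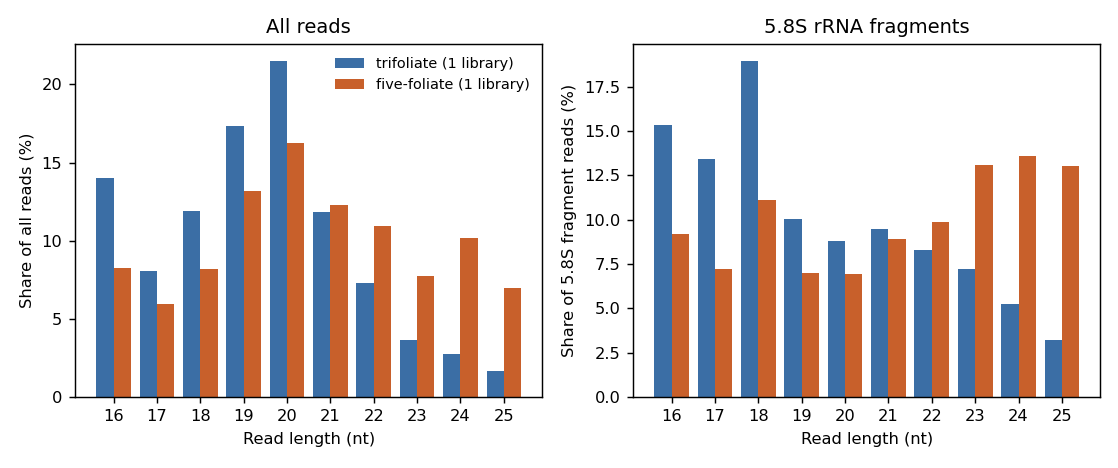
Share of reads by read length (nt) in the trifoliate and five-foliate libraries, for all reads (left) and for reads that are exact parts of 5.8S ribosomal RNA (right), 1 library each. The five-foliate library holds more of the 22- to 25-nt reads in both panels, with 24-nt shares of all reads of 10.2% against 2.74%.

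Fragments of transfer RNA and ribosomal RNA, a sign of RNA breakdown, moved in length in the same direction. Parts of the 5 listed RNAs were 4.31% of trifoliate reads (4.29 to 4.32) and 3.81% of five-foliate reads (3.797 to 3.821). Fragments of the alanine transfer RNA were 3.51% and 2.53%, and 5.8S ribosomal RNA fragments were 0.757% and 1.22%, a ratio of 1.61. The ratios were 1.72 for the glycine, 1.06 for the glutamate and 0.92 (0.84 to 1.01) for the aspartate transfer RNA. The lower total thus reflects the alanine transfer RNA, which supplied most of these reads, and is not shared by all 5 RNAs. For 5 of 5 RNAs the mean fragment was longer in the five-foliate library, by 1.15 to 2.499 nt. Of the 5.8S fragments, 15.7% were 23 to 25 nt long in the trifoliate and 39.7% in the five-foliate library. The libraries also differed in base calling: N-holding tags took 0.911% of trifoliate and 0.0608% of five-foliate reads, and an N at position 7 from the 5′ end was in 68531 and 53 reads.

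The second comparison was of microRNA families. Listed families made up 1.505% of trifoliate and 1.788% of five-foliate reads; 42 of 50 were measured and 37 had 100 or more reads. None was set apart as higher in the five-foliate library and 3 were set apart as lower, namely miR3522, miR408 and miR398. The family miR3522, among the 8 most abundant, fell from 1471 to 215 reads per 1000000 (RPM), a log2 ratio of -2.77 (95% counting interval -2.84 to -2.71). The family miR408, which targets messages of copper proteins such as plantacyanin and laccases, went from 33.6 to 4.39 RPM, a log2 ratio of -2.94 (-3.43 to -2.48). The family miR398, which targets copper/zinc superoxide dismutase messages, went from 13.7 to 2.35 RPM, a log2 ratio of -2.55 (-3.25 to -1.90); its leading tag TGTGTTCTCAGGTCGCCCCTG had 80 reads in the trifoliate and 1 in the five-foliate library, and with exact mature sequences only the family's log2 ratio was -5.11. Over its 9 tags miR398 had 137 and 23 reads. Tags of miR398 other than the leading tag thus held most of its five-foliate reads and fell less than the leading tag. RefSeq lists 1 miR3522, 4 miR408 and 4 miR398 genes. Of the 37 families with 100 or more reads, 26 differed by less than 1.5-fold.

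**Figure D2:**
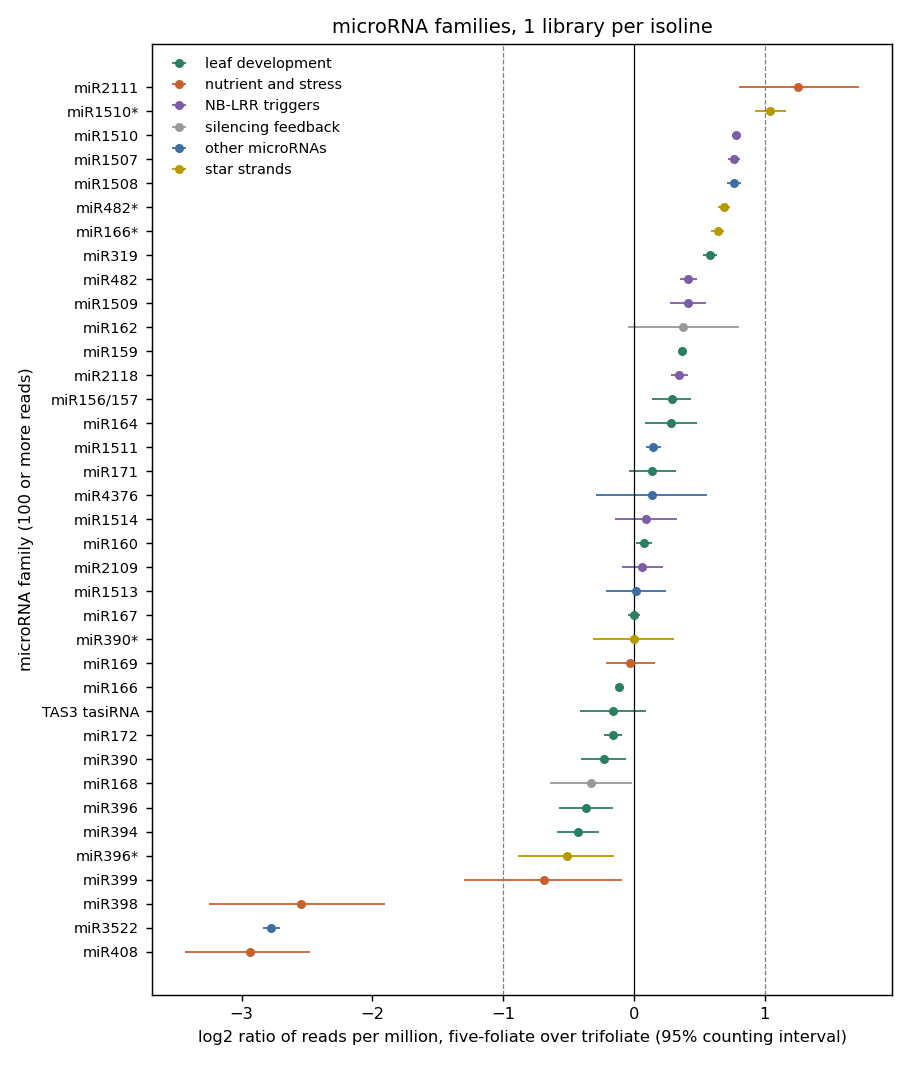
Log2 ratio of RPM (five-foliate over trifoliate) for the 37 microRNA families with 100 or more reads, with exact 95% counting intervals; colours give the list, an asterisk marks a star strand, and dashed lines mark 2-fold. The intervals of miR398, miR3522 and miR408, lie wholly beyond 2-fold, all on the lower side.

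Among the other most abundant families, miR159, which targets MYB transcription factor messages, stood at 4017 and 5194 RPM, a log2 ratio of 0.37. The family miR1510, a 22-nt trigger of silencing of NB-LRR disease resistance genes, stood at 1575 and 2707 RPM (log2 ratio 0.78), and miR1507, of the same kind, at 601 and 1023 (0.77). The star strands of miR482 and miR166 had log2 ratios of 0.69 and 0.64. The family miR166, which targets HD-ZIP transcription factor messages that set leaf polarity, stood at 1872 and 1734 RPM (-0.11), and miR167 at 703.7 and 703.6 (0.00; at or below 0 under every scaling run, and above 0 with both other family definitions). TMM scaling shifts every log2 ratio by -0.22, scaling to reads of 20 to 24 nt by -0.29 and scaling to listed families by -0.25; each of these exceeds the main ratios of miR166 and miR167 in size. Over 8 other scalings and family definitions, miR159, miR1510, miR166 and both star strands kept their sign, and miR1507 changed it under 1, the scaling per read length (-0.01).

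The leaf development list, the one closest to the leaf phenotype, did not stand apart. All 14 families were measured and 0 were set apart; 6 had a log2 ratio above 0 and 8 below, and the median was -0.06, at percentile 42.6 of the random lists matched on reads and 14.2 of those matched also on length. Log2 ratios were 0.58 for miR319, which targets TCP transcription factors of leaf growth, 0.29 for miR156 with miR157, 0.28 for miR164, 0.14 for miR171 and 0.08 for miR160. They were -0.16 for both miR172 and the TAS3 siRNA that targets auxin response factors, -0.23 for miR390, the trigger of that siRNA, -0.37 for miR396, which targets growth-regulating factors, and -0.43 for miR394. The mature forms of miR396 differed: the tag ending in TT had 218 and 132 reads (-0.69), and that ending in TG 180 and 184 (0.06). The family miR393, with 60 and 37 reads, had a log2 ratio of -0.67 (-1.30 to -0.05), which was -1.42 when scaled per read length and -1.19 with up to 2 mismatches. The log2 ratios of miR160 and miR171 are smaller than the TMM shift, which applies to all families alike, so their signs flip with it; that of miR164 flips with the scaling to reads of 20 to 24 nt. The signs of miR167 and miR319 flipped only with the family definition, not with a scaling. For miR319, with exact mature sequences only, its log2 ratio was -0.21.

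The nutrient and stress list was the 1 list far out among random lists. Of its 9 families 6 were measured, 5 had a log2 ratio below 0, and the median was -1.60, at percentile 0.05 of random lists matched on reads and at 0.05 of those matched also on length; with the family that had 0 reads at its floor the median was -1.62. The 2 families set apart were miR398 and miR408. Chosen after its values were seen, miR397, which targets laccase messages, had 26 trifoliate and 0 five-foliate reads, at least 8.5-fold lower against the floor of 3 reads, with an exact interval that begins at 6.43-fold. Also chosen after the values were seen, miR2111, the member above 0, had 59 and 138 reads, a log2 ratio of 1.25 (0.80 to 1.72), and ran from 0.97 to 2.18 over 8 other scalings and family definitions. The other measured members, also given after the values were seen, were miR399 at -0.69 (-1.30 to -0.09) and miR169 at -0.03 (-0.22 to 0.16). The low median thus rests on miR397, miR398 and miR408, and is not shared by the whole list. The percentile takes the members as independent draws, which related microRNAs may not be. Without families under 100 reads the list's median was -0.68.

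The list named for NB-LRR triggers holds miR482, miR1507, miR1509, miR1510, miR1514, miR1515, miR2109 and miR2118. Targets were not checked here, so not every member may be such a trigger. In this list 8 of 8 families were measured, 0 were set apart and 7 had log2 ratios above 0. The median was 0.38 at percentile 80.0 (24.01 when matched also on length). Most of these microRNAs are 22 nt long, and 22-nt tags in general were higher in the five-foliate library: when each read length was scaled by its own median ratio, a choice made after seeing the data, the list's median was -0.36, and the log2 ratios of miR1510 and miR1507 were 0.23 and -0.01. The star strands had a median of 0.67 over 6 families at percentile 88.3 (95.6 when matched also on length), the other microRNAs a median of 0.12 over 6 at 61.3, and the silencing feedback list a median of 0.02 over 2 at 42.3; of these 3 lists, only miR3522 among the other microRNAs was set apart.

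**Figure D3:**
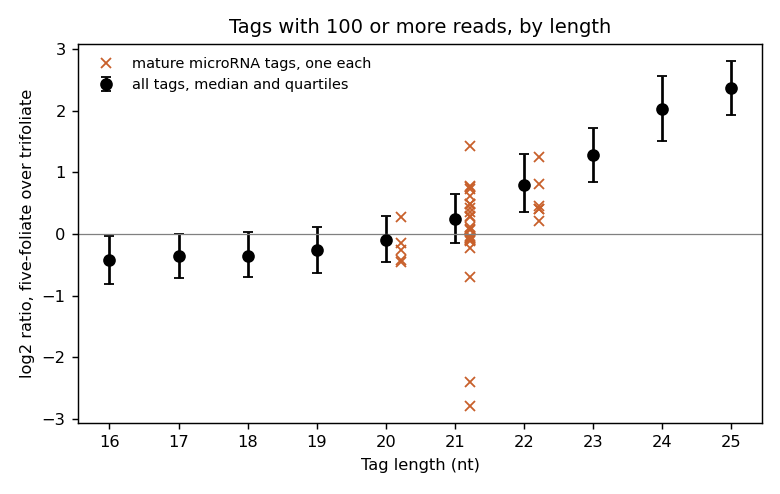
Log2 ratio (five-foliate over trifoliate, 0.5 reads added) by tag length (nt) for tags with 100 or more reads; black points and bars are the median and quartiles of tags without N and near-copies, and crosses are single listed mature microRNA tags of 20, 21 and 22 nt, drawn beside their length. The median rises from -0.42 at 16 nt to 0.25 at 21 nt and 2.36 at 25 nt.

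The third comparison was of single tags. Of 14016 tags with 100 or more reads, 2433 were set apart as higher and 833 as lower in the five-foliate library, so 74.5% of those set apart were higher. The split followed read length: without N tags and near-copies, 2005 of 2833 tags of 23 to 25 nt were higher, and 279 of 7118 tags of 16 to 20 nt were lower. N tags and near-copies supplied most of the lower ones, and without them 2405 tags were higher and 314 lower (88.5% higher). The share that was higher among tags set apart was 63.7% with TMM, 59.1% with scaling to 20 to 24 nt reads, 25.6% (279 higher, 809 lower) with each read length scaled by its own median, and 48.0% (276 higher, 299 lower) with that scaling and without N tags and near-copies.

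The 5 tags with the largest ratios had 0 trifoliate reads. They were AGAGATTGTAGCTTAAAGTGC with 373 five-foliate reads (at least 127-fold higher), TTAACAACAATGAACGTGAGAAGC with 333, TGGACATGAGAACGATGCACGA with 322, TGACAAGGAGACATGAACAGAGAC with 241 and TGGACATGAGAACGATGCACG with 231 (at least 78.6-fold higher). The tags with 322 and 231 reads are the same sequence but for the last base of the longer one. Both hold the five-foliate base of a one-base variant pair (T1G) found in the search described at the end. Beyond the pair itself, tags with the trifoliate base had 95 trifoliate and 0 five-foliate reads. Those with the five-foliate base had 0 and 1409. The 1409 reads include those of the tags with 322 and 231 reads, so they are not wholly separate evidence on these tags. For these tags a higher level and a one-base difference between the lines cannot be told apart. The place of the tags in the genome was not determined here. In the other direction, the 5 tags with the largest ratios had 4363 to 2481 trifoliate and 0 five-foliate reads, and each held an N at position 7. Without N tags and near-copies, the leading 5 lower tags had 674 to 152 trifoliate and 0 five-foliate reads.

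Most abundant tags were in both libraries. Over all 308702 tags 51.9% were shared (51.7 to 52.1), with 40196 seen only in the trifoliate and 108256 only in the five-foliate library. At 10 or more reads 94.8% were shared, and at 100 or more reads 99.1%. Shared tags held 98.4% of the trifoliate and 97.4% of the five-foliate reads.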

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

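The settings named as per read length, without N tags and near-copies, or both were chosen after seeing the data. Of the alternative values for results that answer a comparison, 49 stayed within counting error or 1.5 times the main count and 40 moved beyond it. Of all of them, 10 fell on the other side of no difference, namely 2 of the 21-nt ratio and 8 list medians; the cause was not tested unless stated. No paired analysis was possible because each isoline has 1 library. For the same reason leaving out a library was not possible. The reads by genomic origin were not run, and pseudocounts for normalized values were not needed.

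The 24-nt ratio of 3.71 was 3.51 with tags of 10 or more reads, 3.39 without the top 10 tags, 3.69 without N tags and near-copies and 1.90 over distinct tags. The 21-nt ratio of 1.04 was 1.05, 0.968, 1.04 and 0.780 in the same order, so it changed direction without the top tags and over distinct tags. Breakdown fragments with 1 mismatch allowed took 6.18% of trifoliate and 5.97% of five-foliate reads. Shared tags rose from 51.9% to 94.8% and 99.1% at 10 and 100 reads, and to 99.8% at 100 reads without N tags and near-copies.

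Families set apart as lower (miR398, miR408 and miR3522) were the same 3 under every scaling, family definition and fold limit run; with a minimum of 10 reads miR397 made 4, and with a minimum of 1000 reads 1 was left, miR3522, as the others have fewer reads. Families set apart as higher, 0 in the main count, were 2 (miR2111 and miR1510*) with up to 2 mismatches and 7 with the 1.5-fold limit.

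List medians moved with the scaling. For leaf development (-0.06) they were -0.27 with TMM, -0.084 with median of ratios, -0.30 per listed families and -0.35 per read length. For NB-LRR triggers (0.38) they were 0.16 with TMM, 0.13 per listed families and -0.36 per read length. For other microRNAs (0.12) they were -0.092, -0.12 and -0.15 in that order. Silencing feedback (0.02) was -0.19 with TMM, -0.0057 with median of ratios, -0.23 per listed families and -0.13 per read length, and nutrient and stress (-1.60) was -0.68 with 100 reads or more. The star strand median stayed within its counting interval throughout.

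Tags set apart as higher (2433) were 9558 with 10 reads, 366 with 1000 reads, 1300 at 3-fold, 279 per read length and 276 with that scaling and without N tags and near-copies. Tags set apart as lower (833) were 1272 per 20 to 24 nt reads, 4294 with 10 reads, 125 with 1000 reads, 1610 at 1.5-fold, 506 at 3-fold, 314 without N tags and near-copies and 299 with both added choices. Fewer or more tags are tested under other read minimums. Of 168 alternative values for named families, 96 lay outside the family's counting interval, 72 inside it, and 16 had the other sign. With exact mature sequences miR398 was at -5.11 and miR408 at -2.41. The family miR393 had 97 reads, and its log2 ratio of -0.67 was -1.42 per read length; miR397 stays out of the main count through the 100-read minimum.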

Other observations

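The tests in this part were chosen after the results they bear on had been seen, except that the library scalings, apart from the one per read length, were fixed before the data were examined. Beside the families of the report, tags present in 1 library alone were few, but more than counting gives at read numbers where it rarely misses a tag. Without N tags and near-copies, 96.5% of 72408 tags with 10 or more reads were in both libraries. At 100 or more reads it was 99.8% of 12783. Without N tags and near-copies, 357 tags with 20 or more reads were seen only in the five-foliate library, 265 of them 24 nt long, where counting scaled by read length gives 22.7 on average over all lengths. Only in the trifoliate library were 106 such tags, 22 of them 21 nt long, where it gives 0.0138. The calculation takes 1 ratio for all tags of a length, so tags that vary around it also enter.

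The five-foliate library had longer reads throughout. By reads, a rise of the 24-nt siRNA class alone is argued against, since the 25-nt share rose 4.30-fold and the 24-nt share 3.71-fold. Over distinct tags, however, the 24-nt share rose more (18.2% to 34.6%) than the 25-nt share (4.64% to 5.72%). More reads bring out more rare tags, above all in a class with few reads per tag. In the trifoliate library the 24-nt class held 36448 tags in 273675 reads, and the 25-nt class 9295 in 162538. The distinct-tag contrast therefore cannot separate a 24-nt siRNA difference from a shift in read length. A shift in read length across the whole library, as size selection could give, is consistent with ribosomal and transfer RNA fragments that were longer by at least 1.15 nt in 5 of 5 cases. More RNA breakdown in the trifoliate library stays open: among mature microRNA tags that are not part of a longer and more abundant tag, the median log2 ratio of 6 tags of 22 nt lay 0.69 above that of 3 tags of 20 nt (bootstrap SE 0.32), which is too few tags to decide. A genuine difference in 24-nt siRNAs between the isolines on top of that shift stays open and untested, as does any other difference between the plants.

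The families miR3522, miR408 and miR398 were lower in the five-foliate library. The family miR397, which like miR408 and miR398 has copper protein targets, had 0 reads there. The scalings run do not account for this, since the highest log2 ratio of the 3 families over them was -2.55. That is miR398 on the main scale, and every other scaling moved the 3 families further down. Read length is argued against by the 1497 tags of 21 nt, whose median was 0.25, and GC content by 21-nt tags within 5 points of the families' leading tags, whose lowest median was 0.093. A difference in genotype may lie behind the pattern, or, for miR408, miR398 and miR397 only, one in the copper supply of the plants. With 1 library per isoline the design cannot tell these apart, nor from any other difference between the 2 libraries or their plants. No biological explanation was tested.

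A search for tags that rose 8-fold or more with a neighbour at 1 base that fell 8-fold or more found 5 pairs, such as TATAATCATTTTGTTGCTTCC (123 trifoliate and 0 five-foliate reads) and CATAATCATTTTGTTGCTTCC (1 and 179 reads; T1C, counted from the 5′ end, trifoliate base first). Sequencing errors are argued against as the source, since 2 of the 10 tags had a more abundant neighbour in their own library. Matched control tags gave 9.60 pairs on average when near-copies were allowed as partners, more than the 5 observed, and 0.0020 when near-copies, which none of the 5 lower partners is, were left out, so the count exceeds chance only under the second form, which was added after the first was seen. Sequence differences between the isolines at all pairs are argued against, since 32.9% of the reads of other tags with the trifoliate base came from the trifoliate library, a value set by the pair with A19G. In 3 of the 4 pairs with such tags all 180 reads came from that library, which may reflect sequence differences between the lines or related loci expressed in 1 line, and without a genome these cannot be told apart.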
